A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

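Total RNA from a Saccharomyces cerevisiae mid2 mutant in the BY4741 background was compared between cultures given caspofungin at 15 ng/ml for 2 h and the untreated part of the same culture, both grown at 24 °C in rich medium, per the labels' protocols. RNA of 2 cultures was hybridised to 4 2-colour DNA arrays, with the dyes swapped between the hybridisations of each culture, per the labels. On arrays 1 and 3 the caspofungin RNA carried Cy3 and the untreated RNA Cy5, and on arrays 2 and 4 the dyes were the other way round. The labels do not say which arrays share a culture. The 4 arrays are named by the numbers in their labels.

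The values used are the log2 ratios deposited by the authors, 1 per gene and array. The log base was read from the values: 2 raised to the deposited value lay within 2e-06 of a number with 4 decimals for 100% of the values on each array, against 3.79% to 4.88% when e or 10 was used as the base. The scanner intensities were not used here. The software, the background correction, the within-array normalization, the rule that left cells blank and the genome build are not given in the sources used here. The medians of the genes measured on all arrays were -0.10, -0.06, -0.22 and -0.07 on arrays 1 to 4, so the ratios had not been centred exactly on these genes. Scale between arrays, centring and the direction of the ratios stay unknown.

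The table lists 6207 genes and 2 control rows, and no column was left unused. Gene names were taken from the RefSeq gene table of assembly R64 by systematic name, which matched 5654 names and left 553 under the name in the table. No coordinates are given, because the authors' build is not named. A value was present for 3215, 4346, 3228 and 3538 genes on arrays 1 to 4. The comparisons used the 2925 genes with a value on all 4 arrays, of which 2803 had a matched name. Another 374 genes had values on 3 arrays, 403 on 2, 699 on 1 and 1806 on none. The number of arrays limits the precision.

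A rule for the direction was set before the data were examined: arrays of opposite dye orientation that correlate below 0 across genes would mean ratios that follow the dyes, to be turned by the dye labels, and a correlation above 0 would mean ratios already turned by the authors. The rule did not give 1 answer. Pearson's r between opposite orientations ran from -0.15 to 0.14 with a mean of -0.012, while Spearman's rho ran from -0.33 to -0.12. Taken on the ranks, or on the mean r read strictly, the rule would have turned the values. The values were kept as deposited, a departure from the rule made after seeing the data. Large ratios of the same sign in both orientations were the reason at the time, but dye bias in unturned values would give the same, so they do not decide it. What speaks for the values as deposited is HIS3 and LEU2, disrupted in this strain background, whose ratios alternated with the dyes. They are the 2 genes with 4 values among 5 genes of a deleted-gene list fixed beforehand. Their use for the direction was chosen after seeing the data. The control row 3XSSC went against them, with 1 sign on all 4 arrays (0.26, 0.10, 0.997 and 0.44 on arrays 1 to 4). The control row Arabidopsis read -0.62, 0.10, 0.13 and 0.73. The readings are therefore not separated. Results with the values turned by the dye labels are given as an alternative.

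Each gene was tested with limma 3.58.1 in R 4.3.3 on the means of the 2 cultures against 0, with moderated variances. Because the arrays of a culture are not identified, both pairings that join opposite dye orientations were fitted (arrays 1 and 2 with 3 and 4, and arrays 1 and 4 with 2 and 3), and the larger p of each gene was adjusted by the Benjamini-Hochberg method. The threshold was an adjusted p of 0.05. A separate count took genes changed at least 2-fold with the same sign on every array, with no test. Of 33 gene lists fixed before the data were examined, 29 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01, again with the larger p of both pairings and Benjamini-Hochberg adjustment. Camera compares the genes of a list with all other genes, so a list can pass with a median near 0. The pattern for cytoplasmic ribosomal proteins also took in RPP1, which encodes a subunit of RNase P, and the pattern for transposons matched no gene. The dye effect was tested in the same way on the difference between orientations. For lists it was tested at the preset correlation only, so its calls were not checked with an estimated correlation.

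The genes named are, per direction, the 10 with the largest mean among those past the threshold with the same sign on all 4 arrays, filled where fewer passed by the genes with the largest smallest ratio, then up to 4 genes with the largest absolute mean per list described, and 12 genes fixed by name. Genes named only because they passed over their list alone, or as single members of a small count, were chosen after their values were seen. HIS3 and LEU2 belong to a list fixed beforehand, but their use for the direction was chosen after their values were seen. Errors are SDs over the 4 arrays, which include dye effects and technical repeats. Alternatives covered the pairing, the 4 arrays as replicates, a dye term, a random block, the threshold, a test against 1.2-fold, robust variances, centring, scaling, genes on at least 3 arrays, leaving out each array, the size threshold, the correlation and ranks in camera, and genes shared between lists. Figures were drawn with matplotlib 3.10.9.

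The gene test was tested on simulated data for 2925 genes with the measured dye parts, 200 changed genes and 20 draws. With noise drawn from each gene's own moderated variance, which is the test's own model and favours it, it called 98.9% of genes changed by 1 on the log2 scale and 100% of those changed by 2, and 0.946% of its calls were false. With the noise of other genes in place of their own, it called 86.1% and 98.4%, and 9.18% of its calls were false, above the nominal 5%. The 200 seeded changes ease the adjusted threshold. In the measured data 47 genes had a mean of at least 1 in size and 1 gene passed. The simulated rates therefore do not carry over, and the count of 1 does not show that few genes changed. The list test called a list of 20 genes shifted by 0.5 in all 20 draws and none of 560 unshifted lists under either noise. These simulated genes were independent, so the list test was not checked against correlated genes.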

Results

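Transcript levels of a yeast strain lacking MID2, the gene of a cell surface sensor of the cell wall integrity pathway, were compared with and without caspofungin, an echinocandin that inhibits beta-1,3-glucan synthase. The question was which transcripts of this mutant differ after 2 h at 15 ng/ml. The data are 4 arrays of 2 cultures with swapped dyes, with log2 ratios for 3215, 4346, 3228 and 3538 of 6207 genes on arrays 1 to 4. The 2925 genes measured on all 4 arrays were compared. MID2 itself was blank on all 4 arrays, as were 1806 genes in all, so the blank does not test the genotype.

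HSP12 (YFL014W), which encodes a small membrane-associated stress protein, was the gene that passed the test: its log2 ratio was 3.90 ± 0.67 (SD, n = 4 arrays), a 14.9-fold difference with the same sign on 4 of 4 arrays (limma, adjusted p = 0.0196). No gene with a negative ratio passed. A positive ratio is taken here to mean higher with caspofungin, and up and down below are as deposited. That direction is an assumption, not settled: neither the labels nor the values state it, and it rests on the series being titled by the treated condition and, for ratios that do not follow the dyes, on HIS3 and LEU2 alone. The control row 3XSSC, which kept 1 sign on all 4 arrays, goes against those 2 genes. If the ratios were deposited the other way up, every direction below would turn, and if they follow the dyes, HSP12 no longer passes (0 genes), nor do 8 of the 11 lists that passed, the cell wall integrity signature among them. Cell wall genes are no independent evidence of the direction.

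At an unadjusted p under 0.05, 741 genes differed, 200 with positive and 541 with negative means. All 4 ratios were positive for 201 genes and negative for 565. The median of the gene means was -0.13, and -0.02 with each array centred on its median, which brings it near 0 by construction. After that centring all 4 ratios were positive for 321 genes and negative for 255, and at an unadjusted p under 0.05 there were 334 positive and 230 negative means. Centring itself sets the balance of signs, so neither set of counts shows in which direction more genes differed. HSP12 lost its call when genes with values on at least 3 arrays were tested (limma, adjusted p = 0.154, from 2.0e-05 to 0.154 over its alternatives). Its log2 ratio was the same there, 3.90. The genes added there have values on 3 arrays, so 1 of their cultures rests on 1 array and its dye part does not cancel. Whether that ended the call was not tested. The count of 1 rested on the pairing of arrays: pairing arrays 1 and 4, and 2 and 3, gave 148 genes, pairing 1 and 2, and 3 and 4, gave 1. It was 61 without array 1, 56 without array 3, 10 with arrays centred and 355 with arrays scaled to the same spread, of which 159 had positive and 196 negative means.

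At least 2-fold on every array were 14 genes, all with positive ratios, a count made without a test. Among them were NCW2 (systematic name YLR194C), a cell wall protein gene, with 1.93 ± 0.25, CWP1 (YKL096W), a cell wall mannoprotein gene, with 1.71 ± 0.55, and SED1 (YDR077W), a major cell wall protein gene, with 1.28 ± 0.15 (log2, SD, n = 4). NQM1 (YGR043C), a transaldolase paralogue, had 1.64 ± 0.15, and PUN1 and PRB1, the latter encoding vacuolar proteinase B, had 1.60 ± 0.47 and 1.36 ± 0.28. RTC3 had 2.53 ± 0.56 and YHR138C 1.42 ± 0.30. The ratios of YLR162W (2.25 ± 1.197), GAT1 (1.81 ± 1.03) and the retrotransposon rows YBL101W-A (1.69 ± 1.21) and YBL005W-A (1.88 ± 1.15) were over 1.5 higher on array 3 than on any other array. YGL088W had 1.76 ± 0.56. Near-identical retrotransposon copies can share signal, so those rows are uncertain. PUN1, YGL088W and YBL005W-A were chosen after their values were seen. The count was 25 without array 2, though leaving out an array cannot lower it. It was 3, all negative, with the values turned by the dye labels, an alternative chosen after seeing the data.

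**Figure D1:**
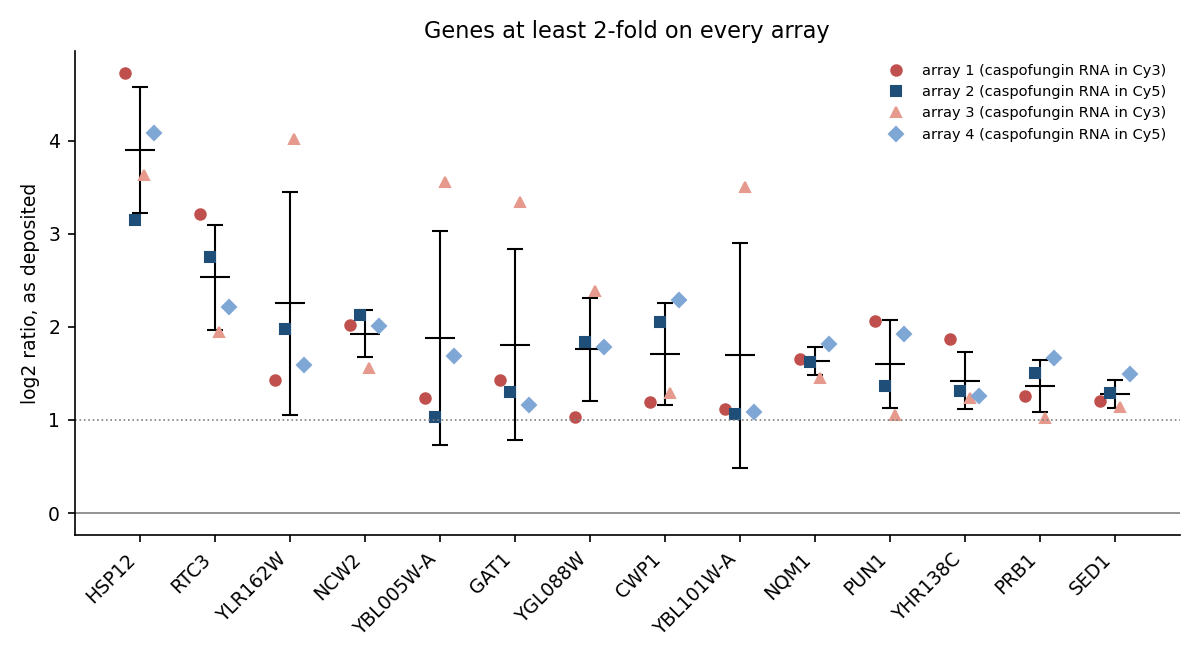
Log2 ratios, as deposited, of the 14 genes at least 2-fold on every array (y axis), with 1 marker per array, a horizontal bar for the mean and whiskers of 1 SD over 4 arrays; the dotted line marks a log2 ratio of 1. HSP12 has the highest mean, 3.90, and YLR162W, GAT1, YBL005W-A and YBL101W-A lie over 1.5 higher on array 3 than on the other arrays.

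The genes that kept a negative ratio on all 4 arrays by the largest margin were MFA1, which encodes the a-factor mating pheromone (-0.76 ± 0.29), OSH7 (-0.75 ± 0.32), NOP9 (-0.61 ± 0.18), VPS63 (-0.57 ± 0.10), TVP38 (-0.83 ± 0.51), DIM1 (-0.53 ± 0.11), KTI12 (-0.56 ± 0.12), CYC1, the gene of cytochrome c isoform 1 (-0.64 ± 0.26), RMD1 (-0.67 ± 0.30) and RAS1 (-0.63 ± 0.15), all in log2 with SD and n = 4. None of these passed (adjusted p = 0.163 for each).

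The cell wall integrity signature, genes known to respond to the Slt2 kinase pathway, shifted upward relative to other genes. Its 21 measured members had a median log2 ratio of 0.49 (camera, adjusted p = 4.4e-14). That call was not kept with an estimated correlation: the adjusted p was 0.896 with one estimated from the culture means and 0.135 with one from the 4 arrays. Estimating it also leaves the test few degrees of freedom, 1 from the culture means. With a dye term the estimate was -0.041, below the preset 0.01, and the call was still lost (camera, adjusted p = 0.336). For this list and those below, a call lost there does not by itself show correlated genes, nor does it secure the call. With the values turned by the dye labels, the median less that of all genes went from 0.62 to 0.09 (camera, adjusted p = 0.752). Of the 21 members, 13 were positive on all 4 arrays. Over all genes 0 of the 21 passed, and adjusted over the list alone 13 passed, all with positive means. NCW2, CWP1 and SED1 led the list, followed by PRM5 with 1.22 ± 0.26. PIR3, a cell wall protein gene, had 0.90 ± 0.32 and CRH1, a chitin transglycosylase gene, 0.86 ± 0.22. YBR071W and BGL2 passed over the list alone with signs that differed between arrays, and YBR071W was named after its values were seen.

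**Figure D2:**
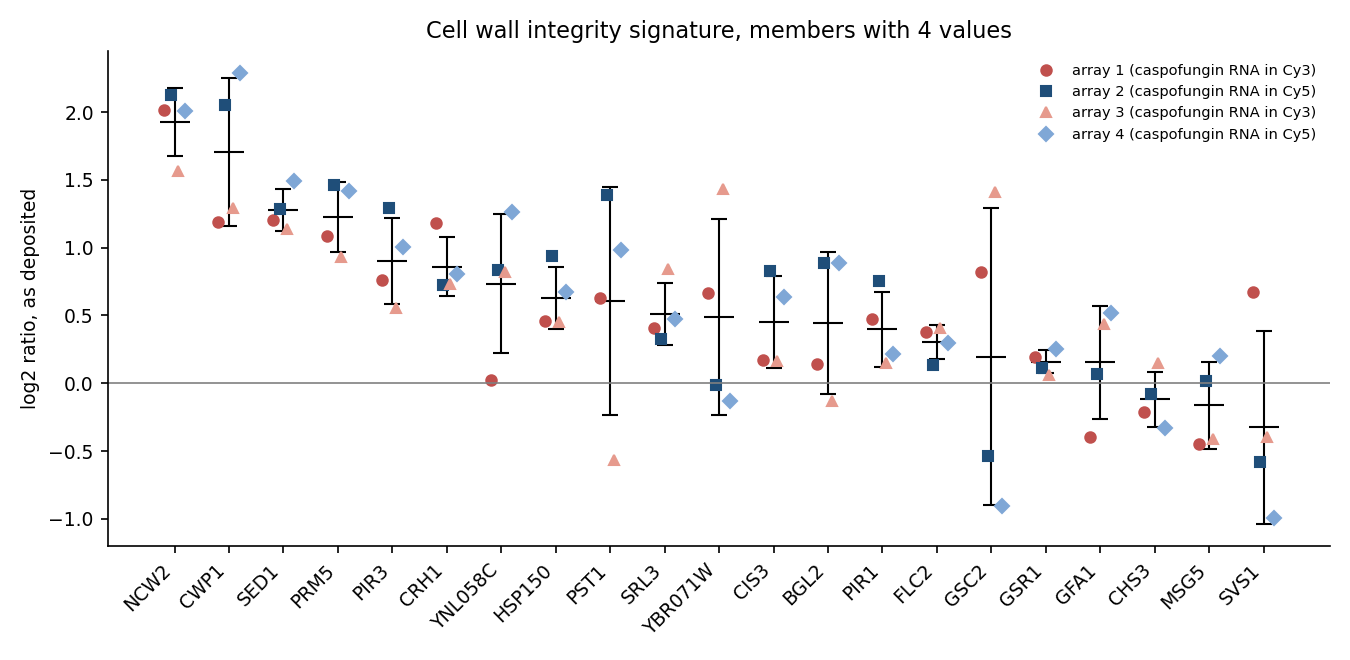
Log2 ratios, as deposited, of the 21 measured members of the cell wall integrity signature (y axis), with 1 marker per array, a horizontal bar for the mean and whiskers of 1 SD over 4 arrays. NCW2 and CWP1 have the highest means, 1.93 and 1.71, and GSC2 is positive on arrays 1 and 3 and negative on arrays 2 and 4.

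The general stress response list also shifted upward relative to other genes, with a median of 0.28 over 23 measured members (camera, adjusted p = 5.0e-14). With an estimated correlation the call was not kept, at an adjusted p of 0.896 from the culture means and 0.150 from the 4 arrays. HSP12 was its 1 member past the test over all genes. Adjusted over the list alone 7 passed, all with positive means: HSP12, RTC3, TFS1 (1.70 ± 0.49), GSY2, a glycogen synthase gene (1.33 ± 0.69), HOR7, HSP26 and DDR48, the last with signs that differed between arrays. CTT1, the cytosolic catalase gene fixed by name, was blank on all arrays.

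Cell wall mannoproteins shifted upward relative to other genes, with a median of 0.18 over 21 members (camera, adjusted p = 1.4e-06). With an estimated correlation the call was not kept, at an adjusted p of 0.503 from the 4 arrays and 0.896 from the culture means. The list also followed the dyes, with medians of 0.11 and -0.11 on arrays 1 and 3 against 0.58 and 0.54 on arrays 2 and 4. Its dye component passed at the preset correlation, the only one tried for it (camera, adjusted p = 0.0149). Its median less that of all genes was 0.31, and moved to 0.51 without array 3 and 0.19 without array 4. Adjusted over the list alone 8 members passed with positive means and TIP1 with a negative one, and CWP1, SED1, PIR3 and PIR5 (0.89 ± 0.82, negative on array 4) were the largest. The call ended when genes of more than 1 list were left out (adjusted p = 0.169).

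Calcineurin and Crz1 targets had a median of 0.21 over 8 members (camera, adjusted p = 0.0014), a call not kept with a correlation estimated from the 4 arrays (adjusted p = 0.355) or from the culture means (0.896). CMK2, a calmodulin-dependent kinase gene, at 1.23 ± 0.33 and RCN2 at 0.61 ± 0.41 passed the threshold adjusted over the list alone. The median less that of all genes was 0.34, and moved to 0.56 without array 2 and 0.54 without array 4. It fell to 0.23 without array 1 and 0.26 without array 3, where the list only just passed (camera, adjusted p = 0.0497 and 0.0469).

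Glycolysis and fermentation genes had a median of 0.01 over 25 members (camera, adjusted p = 0.0015), a call not kept with a correlation estimated from the 4 arrays (adjusted p = 0.503) or from the culture means (0.896). The list was led by the hexose transporter gene HXT2 (0.74 ± 0.32) and the aldehyde dehydrogenase gene ALD6 (0.64 ± 0.19), and 0 members passed over the list alone. Autophagy and vacuolar proteolysis had a median of 0.24 over 8 members (camera, adjusted p = 0.0015), a call not kept with a correlation estimated from the 4 arrays (adjusted p = 0.503) or from the culture means (0.896). Its medians were 0.07 and -0.16 on arrays 1 and 3 against 0.55 and 0.54 on arrays 2 and 4, and its dye component did not pass (adjusted p = 0.242). PRB1 was past the threshold adjusted over the list alone. The median less that of all genes was 0.37, and 0.21 with genes on at least 3 arrays (adjusted p = 0.0096).

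Osmotic stress and glycerol genes had a median of 0.10 over 12 members (camera, adjusted p = 0.012) and chitin synthesis 0.11 over 10 (adjusted p = 0.020). Neither call was kept with an estimated correlation, at an adjusted p of 0.439 and 0.490 from the 4 arrays and 0.896 for both from the culture means. The osmotic call also ended without genes of more than 1 list (adjusted p = 0.169). HOR7 (1.28 ± 0.60) and RCR1 (1.15 ± 0.23) passed adjusted over the list alone. RCR1 is known for resistance to the dye Congo red. Without arrays 2 and 4 the adjusted p was 0.0746 and 0.0552 for autophagy and 0.0772 and 0.0525 for osmotic stress, and without arrays 2, 3 and 4 it was 0.111, 0.165 and 0.185 for chitin synthesis. The chitin median less that of all genes was 0.24, and 0.25, 0.10 and 0.16 without arrays 2, 3 and 4, and 0.00198 turned by the dye labels (adjusted p = 1). For osmotic stress it was 0.23, and 0.21 without array 2 and 0.27 without array 4. For autophagy it was 0.37, and 0.31 without array 2 or array 4.

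Heat shock chaperones had a median of 0.05 over 20 members (camera, adjusted p = 0.0045) and proteasome genes 0.000872 over 31 (adjusted p = 0.042). Neither call was kept with an estimated correlation, at an adjusted p of 0.772 from the 4 arrays and 0.896 from the culture means for both. No member of either list passed over the list alone (0 members). Both lists followed the dyes: the median of heat shock chaperones was 0.46 and 0.21 on arrays 1 and 3 and -0.30 and -0.11 on arrays 2 and 4, and that of the proteasome 0.40 and 0.05 against -0.29 and -0.09. The dye component itself passed in both lists at the preset correlation, the only one tried for it (camera, adjusted p = 0.000463 and 0.000805). TCA cycle and respiration genes had a median of -0.01, opposite in sign to the direction of their test against other genes (37 members, adjusted p = 0.042), a call not kept with an estimated correlation (adjusted p = 0.772 from the 4 arrays and 0.896 from the culture means). All 3 calls of this paragraph also ended without genes of more than 1 list, at an adjusted p of 0.0724 for heat shock and 0.0573 for the proteasome and TCA genes. The proteasome and TCA lists share no gene with another list, so their shifts were unchanged and the adjustment over lists ended their calls. Less the median of all genes, heat shock was 0.16 there, against 0.18. Leaving out an array ended calls: adjusted p was 1 and 0.996 for heat shock and 0.569 and 1 for the proteasome without arrays 1 and 3, and at least 0.179 for TCA genes without each array. Less the median of all genes, the heat shock median of 0.18 became 0.08 without array 1, 0.34 without array 2 and 0.10 without array 3, the proteasome median of 0.13 became -0.02 without array 1 and 0.23 without array 2, and the TCA median of 0.12 became 0.06 without array 1.

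**Figure D3:**
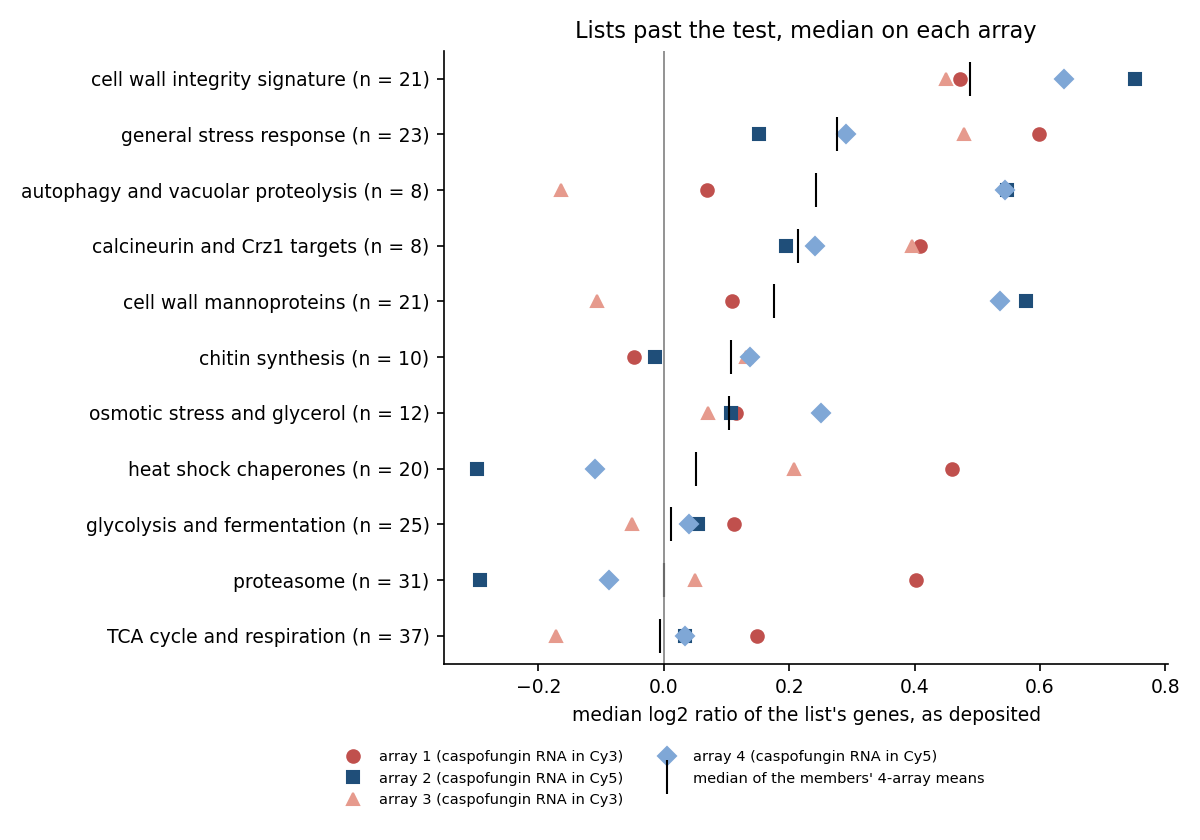
Median log2 ratio, as deposited, of the genes of the 11 lists past the test (x axis), with 1 marker per array and a vertical bar for the median of the members' means over 4 arrays; n is the number of measured members. The cell wall integrity signature lies above 0 on all 4 arrays, and the heat shock and proteasome medians change sign between the dye orientations.

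The other 18 tested lists did not pass. Ribosome biogenesis had a median of -0.16 over 58 members (adjusted p = 0.268). Of these 58, 15 were negative on all 4 arrays, beside 19.3% of all genes compared. The list followed the dyes, with medians of 0.03 and 0.01 on arrays 1 and 3 against -0.50 and -0.27 on arrays 2 and 4 (dye component at the preset correlation, camera, adjusted p = 5.5e-06). It passed without array 1 (adjusted p = 0.00716) and without array 3 (0.000243), which leaves the dyes unbalanced, with arrays scaled (0.0198) and turned by the dye labels. Cytoplasmic ribosomal proteins had -0.11 over 130 (adjusted p = 0.428) and passed without array 3 (0.0499), and their dye component passed too at the preset correlation (camera, adjusted p = 0.0174). Their median lay 0.0161 above that of all genes, opposite in sign to the downward test. The pheromone list had -0.27 over 15 members (adjusted p = 0.370), with MFA1 and AGA2 (-0.85 ± 0.43) past the threshold adjusted over the list alone. In the unfolded protein response list (median -0.05 over 16, adjusted p = 0.177), HAC1 (1.01 ± 0.37) and INO1 (0.72 ± 0.23) passed over the list alone. Beta-glucan synthesis and remodelling had -0.03 over 16 (adjusted p = 0.249), with CRH1 and BGL2 positive and NCA3 and GAS2 negative past the threshold adjusted over the list alone. Adjusted p was 0.129 for cell separation, 0.166 for sulfur metabolism (0.0306 without array 1), 0.198 for ergosterol synthesis, 0.215 for histones, 0.268 for the G1 to S list, 0.288 for the phosphate regulon, 0.368 for amino acid biosynthesis, 0.485 for the iron regulon, 0.648 for oxidative stress, 0.664 for secretion and glycosylation, 0.733 for drug resistance and 0.750 for the G2 to M list. Cell wall integrity signalling had opposite directions in the pairings and was given an adjusted p of 1. The median was negative and the mean positive in the sulfur, unfolded protein response and phosphate lists.

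Among the genes fixed by name, SLG1, the sensor also called WSC1, had -0.44 ± 0.24 and CHS3, a chitin synthase gene, -0.12 ± 0.20 (n = 4). The glucan synthase gene GSC2, also called FKS2, had 0.20 ± 1.10, positive on arrays 1 and 3 and negative on arrays 2 and 4, and its mean was -0.19 without array 1 and -0.34 without array 3. None of these passed. SLT2, the kinase gene, had 0.56 ± 0.41 on 3 arrays, FKS1 0.31 ± 0.27 on 2 and RLM1 -0.24 ± 0.25 on 2, without a test. Markers of other cell types were little measured: 0 alpha-cell genes and 1 sporulation gene, ZIP1 (-0.15 ± 0.23), had 4 values.

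The dye swap was set against the caspofungin signal in the same genes. Arrays of the same orientation correlated across genes at Pearson's r = 0.65 and 0.79, and arrays of opposite orientation at -0.15 to 0.14 (Spearman's rho -0.33 to -0.12). Genes are not independent replicates. Signs followed the dyes in 577 genes one way and 392 the other, against 201 and 565 genes with 1 sign on all arrays, and the SD between genes was 0.327 for both the dye part and the shared part. No gene passed for a dye effect (0 genes, limma, lowest adjusted p = 0.0763), 944 did at an unadjusted p under 0.05, and 237 passed when arrays were centred. HIS3 and LEU2, disrupted in this strain background, alternated with the dyes: HIS3 read -0.63, 0.40, -0.64 and 0.39 and LEU2 -0.58, 0.24, -0.64 and 0.25 on arrays 1 to 4.

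**Figure D4:**
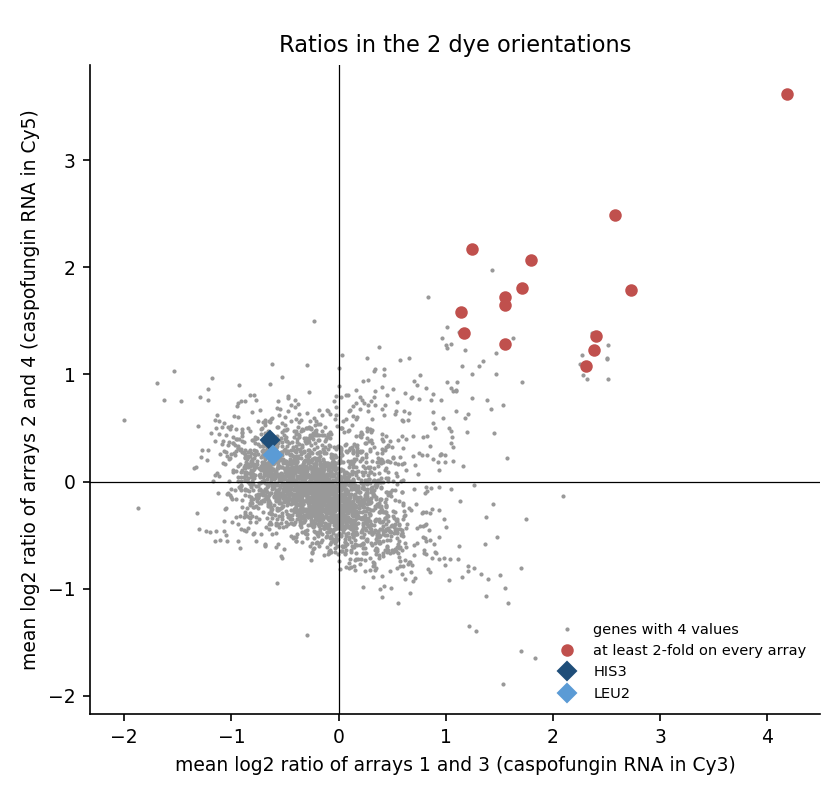
Mean log2 ratio, as deposited, of arrays 1 and 3 (x axis) against that of arrays 2 and 4 (y axis), with 1 point per gene for the 2925 genes with 4 values. The 14 genes at least 2-fold on every array lie in the upper right, and HIS3 and LEU2 lie left of 0 and above 0.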

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

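The tests of explanations in this part, except that of gene length, were chosen after the results were seen. Of 54 results with 4 values, 6 had 1 array far from the others. For independent values the cut used gives about 1 in 20, or 2.7. Arrays of the same dye orientation correlate and the results share arrays, so 2.7 is not the chance count for these results. The 6 were YHR138C (1.87 on array 1), GAT1 (3.34 on array 3), YBL101W-A (3.50 on array 3), DIM1 (-0.70 on array 1), and the medians of ergosterol synthesis (-0.40 on array 3) and the iron regulon (-0.41 on array 3). Outside the 2925 genes compared, 534 genes had values on 2 or 3 arrays in both dye orientations, and 4 of them were at least 2-fold with 1 sign and beyond both control rows on those arrays. Their mean log2 ratios were 1.28 for ENA5 (2 arrays), 4.13 for YFL013W-A (3 arrays), -3.37 for CDC55 (2 arrays) and 1.51 for DIA1 (2 arrays). The CDC55 values were -5.71 and -1.04.

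The 14 genes at least 2-fold on every array kept 1 sign in both dye orientations. If the authors had left the values unturned, HIS3 and LEU2 would keep 1 sign on all arrays, since genes disrupted in both RNAs of an array leave dye bias or background. Their alternating part was 0.471 on average, against at most 0.0219 between pairs of arrays, which taken alone argues against unturned values, although it rests on 2 genes and HIS3 is only partly deleted in BY4741. The control row 3XSSC kept 1 sign, at 0.26, 0.10, 0.997 and 0.44 on arrays 1 to 4, which unturned values would give. Unturned values therefore stay open. Chance agreement between the orientations was examined by reassigning genes at random between them: 0 of 10000 draws gave 14 genes, and the highest gave 5. The draws treat genes as independent and alike in spread, whereas the 14 include the near-identical retrotransposon rows YBL101W-A and YBL005W-A. They show more agreement than between unrelated genes, but do not exclude chance within a gene. A response to caspofungin stays open as a hypothesis, and so does a table deposited as untreated over treated, which no value here decides.

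The 11 retrotransposon Gag (TYA) rows, identified after their values were seen by their names and gene length, were positive on all arrays, with medians of 1.26, 0.82, 3.50 and 1.64 on arrays 1 to 4 (lowest adjusted p = 0.163). Their median over arrays 1, 2 and 4 was 1.202, and the lower of their medians with caspofungin RNA in Cy5 was 0.816. These rows were noticed because they were positive on every array, which made positive values of both measures likely beforehand. Neither value therefore decides on array 3 alone or dye bias as the cause, and the height on array 3 stays unexplained. Of 13 rows of the longer Gag-Pol (TYB) reading frame, 1 was positive on all 4 arrays, and their medians were 0.96, -0.34, 1.52 and -0.07. A single signal shared by near-identical copies was to keep the SD between these rows under 0.5 of that between all genes on each array. The highest ratio was 0.693, on array 4, and the lowest 0.214. The bound as written would exclude sharing, but it was chosen after the values were seen and 1 array decides it, so sharing of signal between copies stays open, and so does a response to caspofungin.

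Many ratios alternated with the dye orientation. Gene length as the cause was to give an absolute Spearman rho of at least 0.2 across genes, and rho was -0.116 over 2803 genes with a length. That argues against length as the main cause of the alternating part. The part shared by both orientations had a larger rho with length, 0.174, also under the bound. Its median was -0.15 in the 702 shortest genes and -0.06 in the 700 longest, so the shared ratios carry a length trend too. The authors' normalization was not tested, since no scanner intensities were used here, and no biological explanation was tested for a component that follows the dyes.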

How the results depend on the processing

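Tests with values turned by the dye labels, without TYA rows, or with a correlation estimated from the 4 arrays were chosen after seeing the data. The count of 1 gene at adjusted p 0.05 became 148 (94 positive, 54 negative) with arrays 1+4 and 2+3 paired, 17 with 4 arrays as replicates, 109 (60 and 49) with a dye term, 460 (157 and 303) with a random block, 11 at adjusted p under 0.10, 10 with arrays centred, 355 (159 and 196) with arrays scaled, 0 with genes on at least 3 arrays, 0 turned by the dye labels, and 1 to 61 when leaving out each array (61 without array 1, 56 without array 3, 1 without array 2 or 4). Leaving out an array leaves the dyes unbalanced, and so does adding genes with values on 3 arrays. The random block had correlations of -0.70 and -0.67, since swapped arrays oppose each other, and counts technical swaps as information. The 14 genes at least 2-fold became 41 at 1.5-fold, 46 (45 and 1) by the mean, 3 turned by the dye labels and 15 to 25 when leaving out each array (25 without array 2). They became 20 with arrays centred, 11 with arrays scaled and 15 with genes on at least 3 arrays. Leaving out the TYA rows took YBL101W-A and YBL005W-A from the 14. The 11 lists became 0 with each estimated correlation (from culture means, which leave 1 degree of freedom, from 4 arrays, and with a dye term), 6 without genes of more than 1 list (ending mannoproteins, osmotic stress, heat shock, the TCA cycle and the proteasome), 9 (8 up, 1 down) with arrays scaled (ending heat shock, the TCA cycle and the proteasome, with ribosome biogenesis gained), 9 with 4 arrays as replicates (ending the TCA cycle and the proteasome), 10 with genes on at least 3 arrays (ending the TCA cycle), 10 by ranks (ending osmotic stress), 5 (1 up, 4 down) turned by the dye labels (of the 11, mannoproteins passed upward and heat shock and the proteasome downward, and 8 did not pass), and 7 to 10 when leaving out each array. The wall integrity signature, mannoproteins, general stress, glycolysis and calcineurin lists passed in each of these 4 left-out fits. The calcineurin list only just passed without array 1 and without array 3 (camera, adjusted p = 0.0497 and 0.0469). Without genes of more than 1 list, medians less that of all genes went from 0.31 to 0.11 for mannoproteins and from 0.23 to 0.16 for osmotic stress. Heat shock went from 0.18 to 0.16, and the TCA and proteasome lists, which share no gene with another list, did not move. Relative to all genes, list medians changed sign in 28 of 464 comparisons, 18 of them in lists past the test in neither setting. The other 10 were -0.0185 for the proteasome without array 1 (0.229 without array 2) and, turned by the dye labels, -0.19 for general stress, -0.27 for heat shock, -0.0419 for glycolysis, -0.0423 for the TCA cycle, -0.21 for calcineurin, -0.25 for the proteasome and -0.00502 for osmotic stress, and, for cytoplasmic ribosomal proteins, -0.0345 without array 3 and -0.0964 turned. The dye effect went from 0 to 237 genes with centring. Of 175 comparisons of named genes, 126 kept their side of the threshold, 48 gained a call and 1 lost it, and 2 changed sign, both GSC2, which passed in neither (-0.19 without array 1 and -0.34 without array 3). Except where stated, the cause was not tested. HSP12 kept its sign in the 7 settings that tested it, and lost its call with genes on at least 3 arrays, where its log2 ratio was the same. Values turned by the dye labels were not among the settings for named genes. Turned in this way, the mean of HSP12 was -0.28, so its sign depends on the direction of the ratios. Keeping each probe apart was not run, since each gene has 1 value. Each ratio already compares the treated and untreated parts of a culture, so the test is paired. Signal over background was not used here.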

Other observations

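Some members of lists that did not pass had positive ratios on all 4 arrays and passed adjusted over their own list alone. PHO89, a phosphate transporter gene, had a log2 ratio of 0.82 ± 0.20, MET6, the methionine synthase gene, 0.73 ± 0.17, NCP1, the gene of NADP-cytochrome P450 reductase, 0.71 ± 0.37 and CTS1, an endochitinase gene, 0.47 ± 0.30 (SD, n = 4). PRY3 of the cell separation list had -0.41 ± 0.19. None passed over all genes (adjusted p = 0.163 for each).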
